A study of Mus musculus with 18 samples.

How the data were processed

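TIF-seq2, which reads the 5′ end and the 3′ end of the same mRNA molecule, was applied to primary myoblasts from the gastrocnemius muscle of female wild-type mice that had fused into myotubes during 24 h with 1 µM of the ERK inhibitor SCH772984, per the labels' protocols. For polysome profiling, lysates were run on 10 to 50% sucrose gradients after 5 min in 100 µg/ml cycloheximide and pooled into a ribosome-free, a light (2 to 5 ribosomes) and a heavy (6 or more ribosomes) fraction, with 2 mice per fraction and 6 libraries in all. For the decay assay, transcription was stopped with 7.5 µg/ml actinomycin D and RNA was taken at 0, 3, 6 and 12 h, with 3 mice per time and 12 libraries in all.

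The submitters' processing notes list bcl2fastq 2.20.0, cutadapt 1.16, UMI-tools 0.5.4 and STAR 2.5.3a, and the mouse build GRCm39. How ends were clustered, how molecular identifiers entered the totals and how TE and half-life were computed are not given in the sources used here. The authors deposited 1 table per assay with 1 row per isoform, defined by its 5′ and 3′ end. Each row of the deposited tables holds a whole-number coverage count with no column for a single library, an annotation class, the distances of both ends from annotated ends, the UTR sequences, and 1 derived value, named TE in the polysome table and half-life in the decay table. The polysome table lists isoforms from a count of 11 up and the decay table from a count of 21 up, as the deposited values show. The number of columns with values of a single library is 0, so depth per library is unknown. The unit of the half-life is not stated; the labels give times in hours. TE carries no unit either, and whether it was scaled by transcript length is not given in the sources used here.

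Because of this, the comparisons of fractions and of times per gene, the isoform usage tests, the 15 gene lists and the rule for named genes, all fixed before the data were examined, were not run here. The comparisons fixed at the same time that the tables allow were kept, with TE in place of the ratio of heavy to free fraction and half-life in place of the decay slope: UTR features, the product of UTR lengths, longer against shorter 3′ ends (at least 100 nt apart) and 5′ ends (at least 20 nt apart), and TE against half-life. Of the UTR features, length, GC content, upstream AUGs and a TOP start were named then, and the others were added later. The coverage minimum of 30, the motif definitions, the way isoforms were joined into loci, the rule of 1 pair per locus, the comparison of new with annotated ends and the classes of upstream AUGs were chosen after the tables had been looked at. The deposited tables pair no isoform with a gene name. The reference table at hand is of build GRCm38, and 0.281% of nuclear ends lay within 3 nt of one of its gene boundaries, so it was not used to name genes and positions are given as deposited.

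Isoforms of the same strand were joined into a locus when they shared an end, or when they overlapped and shared the 20 nt before the start codon or after the stop codon. Analyses used nuclear isoforms with a coverage of at least 30, both UTR sequences and a value above 0. That left 3510 isoforms of 2170 loci with TE (91.8% of the polysome coverage) and 4822 isoforms of 2910 loci with a half-life (95.3% of the decay coverage). Values below 0, 58 for TE and 50 for half-life, were left out. Their median coverage was 12 and 24 and their highest 15 and 240, so not all of these half-lives had low counts. What a half-life below 0 stands for is not given in the sources used here.

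Features were the length and GC content of each UTR, upstream AUGs, a terminal oligopyrimidine (TOP) start (C and then 4 pyrimidines), a purine at position -3, AUUUA pentamers, a Pumilio motif, sites for miR-1, miR-133 and let-7, and AAUAAA in the last 40 nt. Spearman's rho was computed across isoforms, with 95% intervals from resampling whole loci. Its p came from two-sided permutation tests with 100000 permutations on the most covered isoform of each locus, adjusted by Benjamini-Hochberg over the 26 relations. The smallest p these can give is 1e-05. Adjusted rho values used ranks corrected for both UTR lengths and coverage. The decay coverage is pooled over all times and may itself rise with half-life, so this correction can remove part of a relation with half-life. Isoforms and loci are not independent replicates, so these p-values and intervals describe spread across loci, not across mice.

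Pairs of isoforms had the same end and UTR on 1 side and nested UTRs on the other, so that start codon, stop codon and the shared UTR were equal; splicing between these ends is not given in the tables. The pair with the highest lower coverage was kept per locus, log2 of longer over shorter was tested by a two-sided sign-flip permutation test of the mean (exact up to 16 loci), and medians carry bootstrap intervals (1000 resamples). These tests were adjusted together over 24 groups of pairs. Shares carry Wilson 95% intervals, which cover counting error only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

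The tests were tried on simulated values for the real isoforms, 100 times per table. With no effect planted, 4.38% of feature tests for TE over 2170 loci and 6.38% for half-life over 2910 loci gave p under 0.05. A shift of -0.15 log2 planted in 3′ pairs was detected in 91% of simulations for the 149 TE loci and in 99% for the 287 half-life loci. The simulated noise was normal, independent between loci and equal at any coverage, unlike the real half-lives. These shares therefore check the calculation and not how the tests behave on the real values. Alternatives were other coverage minimums, distances, units and adjustments.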

Results

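The study mapped both ends of single mRNA molecules in mouse myotubes to relate them to translation and stability, per its title and design. The polysome table listed 7123 isoforms of 3087 loci with a summed coverage of 1601919 over 6 libraries, and in the decay table there were 6636 isoforms of 3423 loci with a summed coverage of 3121491 over 12 libraries. Median coverage per isoform was 33 and 70. In total 2458 isoforms with the same ends occurred in both tables and held 69.1% of the polysome and 70.6% of the decay coverage, and their coverage in the assays had a Spearman's rho of 0.723. Several isoforms were found in 1523 loci of the polysome table (49.3%) and 1419 of the decay table (41.5%). Median UTR lengths in the polysome table were 111 nt (5′) and 334 nt (3′). TE, the authors' value per isoform, had a median of 0.000743 (95% interval 0.000718 to 0.000765) over the 3510 isoforms used. The half-life had a median of 10.8 (10.7 to 10.97) over 4822 isoforms. Between the 5th and the 95th percentile TE spanned 6.08-fold and half-life 3.00-fold. The deposited tables hold no value per mouse, so no difference could be set against the spread between mice.

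Annotated transcripts made up 50.3% of polysome isoforms (Wilson interval 49.1 to 51.4%) and 68.1% of the coverage. Isoforms with a new transcription start site (TSS) made up 25.1%, those with a new polyadenylation site (PAS) 15.6%, those with both 6.84%, and intergenic isoforms 2.18%. In the decay table the shares were 51.8, 22.5, 17.6, 6.09 and 2.03%. Most new ends lay inside annotated transcripts: 1561 polysome isoforms differed only by a shortened 5′ end and 229 only by an extended one, with 856 and 253 for the 3′ end. An AAUAAA or AUUAAA hexamer, the signal read by the cleavage and polyadenylation machinery, stood in the last 40 nt of 82.9% of annotated 3′ UTRs (81.7 to 84.2%) in the polysome table. New PAS isoforms had it in 58.2% (54.98 to 61.3%; adjusted p = 8.7e-53, Fisher's exact test) and new TSS isoforms in 87.0% (85.3 to 88.5%; adjusted p = 0.000222). The decay table gave 84.2% for annotated and 62.8% for new PAS isoforms (adjusted p = 2.5e-45, Fisher's exact test). Isoforms that share a 3′ end were counted separately, so these p-values are too small. Adenine was the first base of 58.6% of 5′ UTRs, and a purine stood at -3, the main position of the Kozak context, in 82.8%.

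mRNAs with long UTRs had lower TE. Isoforms with 3′ UTRs of at most 150 nt had a median TE of 0.000999 (0.000923 to 0.00105, 957 isoforms), and those above 1200 nt had 0.000433 (0.000382 to 0.000467, 255 isoforms). For 5′ UTRs the medians fell from 0.000867 (0.000833 to 0.000916) at up to 50 nt to 0.000540 (0.000496 to 0.000578) above 400 nt. Across isoforms, Spearman's rho with TE was -0.439 (-0.485 to -0.379) for 3′ UTR length and -0.261 (-0.298 to -0.227) for 5′ UTR length, each with an adjusted permutation p of 2.4e-05, from the smallest p the permutations can give. Of 13 features, 10 passed the adjusted threshold, all with lower TE: besides both lengths these were GC content of both UTRs, upstream AUGs, AUUUA pentamers, Pumilio motifs and sites for miR-1, miR-133 and let-7. After correction for both UTR lengths and coverage 5 passed: both lengths, 5′ GC content (-0.107, -0.149 to -0.0653), upstream AUGs (-0.143, -0.187 to -0.104) and a TOP start (-0.0770, -0.113 to -0.0431). The TOP start, which marks mRNAs of the translation machinery, had a rho of 0.0109 before correction. None of the microRNA sites passed after correction; let-7 came closest, at -0.0401 (-0.0772 to -0.00361; adjusted permutation p = 0.0521). A scaling of TE by transcript length would alone lower TE in isoforms with longer UTRs, and the formula is not given in the sources used here.

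**Figure D1:**
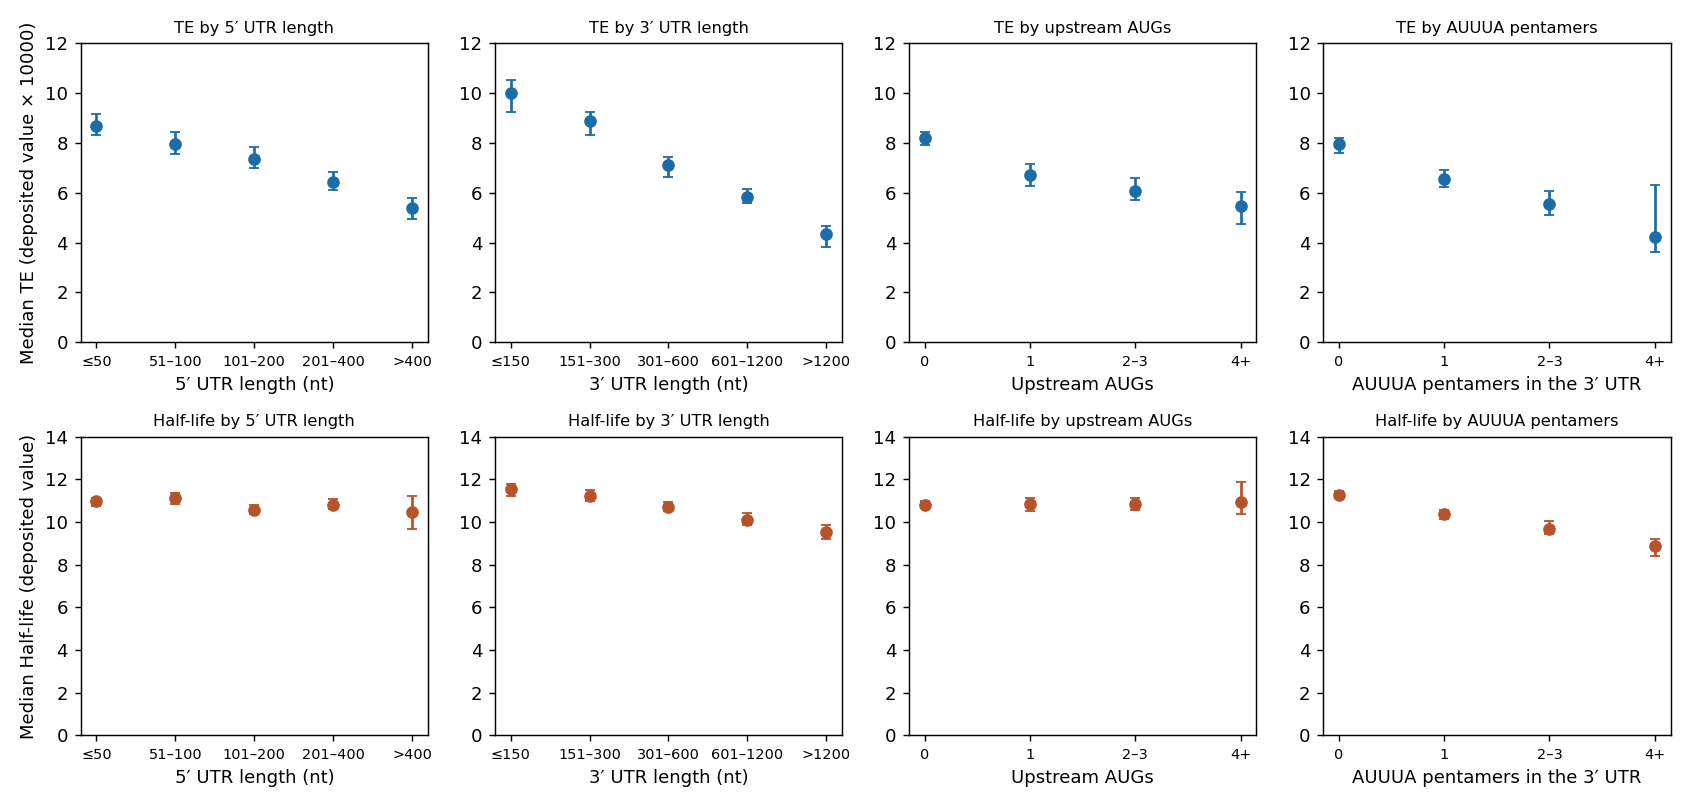
Median TE (upper row, deposited value times 10000) and half-life (lower row, deposited value) of isoforms grouped by 5′ and 3′ UTR length in nt, by upstream AUGs and by AUUUA pentamers; bars are 95% intervals from resampling loci. Median TE fell over all 4 groupings, and half-life fell with 3′ UTR length, from 11.5 to 9.54, and with pentamers, from 11.3 to 8.89.

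Upstream AUGs, which can start translation ahead of the main reading frame, went with lower TE in a graded way. The median was 0.000821 (0.000794 to 0.000846) in 2110 isoforms without one, 0.000671 (0.000627 to 0.000716) in 649 with 1, and 0.000548 (0.000475 to 0.000603) in 270 with 4 or more. Isoforms whose upstream AUGs all met an in-frame stop codon inside the 5′ UTR had a median of 0.000590 (0.000550 to 0.000614, 737 isoforms), and those with at least 1 upstream AUG without such a stop 0.000674 (0.000637 to 0.000729, 663 isoforms). After correction for UTR lengths and coverage, 1 isoform per locus, the first class differed from isoforms without upstream AUGs by -0.291 SD (adjusted p = 6e-05, permutation test, from the smallest p the permutations can give). The class without a stop differed from them by -0.103 SD (adjusted permutation p = 0.142) and from the class with stops by 0.188 SD (adjusted permutation p = 0.0441).

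Within loci, isoforms with the longer 3′ UTR had the lower TE. Over 149 loci with the same 5′ end, start and stop codon, the median log2 difference was -0.42 (-0.53 to -0.34), a ratio of 0.748, and TE was lower in 130 loci (87.2%; adjusted p = 4e-05, permutation test). The difference grew with the added length, from -0.12 (-0.26 to -0.06, 39 loci) for 100 to 200 nt to -0.85 (-0.94 to -0.70, 42 loci) above 800 nt. Pairs with 3′ ends under 50 nt apart, the nearest thing to a repeat measurement in the table, had a median of -0.01 (35 loci) and an SD of 0.399. Among pairs with a coverage of at least 300, the largest fall was on chromosome 7, minus strand, where the isoform from 44775347 to 44778160 (23 nt of 3′ UTR, TE 0.00180, coverage 1782) was compared with the one from 44774989 (381 nt, TE 0.000771, coverage 504). The largest rise was on chromosome 10, plus strand, where TE was 0.000207 for the isoform from 81012480 to 81018189 (273 nt) and 0.000258 for that ending at 81018329 (413 nt), a log2 difference of 0.31, within the SD of near-identical pairs. These 2 loci were picked by their values.

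Isoforms starting further upstream also had lower TE. Over 325 loci with the same 3′ end, start and stop codon the median log2 difference was -0.13 (-0.18 to -0.07), and TE was lower in 200 of them (61.5%; adjusted p = 4e-05, permutation test). The difference was -0.06 (-0.13 to 0.03, 140 loci) for 20 to 50 added nt and -0.34 (-0.61 to -0.05, 40 loci) above 200 nt. Pairs with 5′ ends under 20 nt apart had a median of -0.09 (-0.21 to 0.00, 16 loci; adjusted p = 0.259, exact sign-flip test), no smaller than that for 20 to 50 nt. It was concentrated in the 105 loci whose added sequence brought an upstream AUG, with a median of -0.37 (-0.45 to -0.20), against -0.04 (-0.11 to 0.03) in the other 220 loci (adjusted p = 6e-05 for the difference, permutation test over 6 tests). At equal added length the gain of an upstream AUG went with -0.23 log2 (-0.36 to -0.09).

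**Figure D2:**
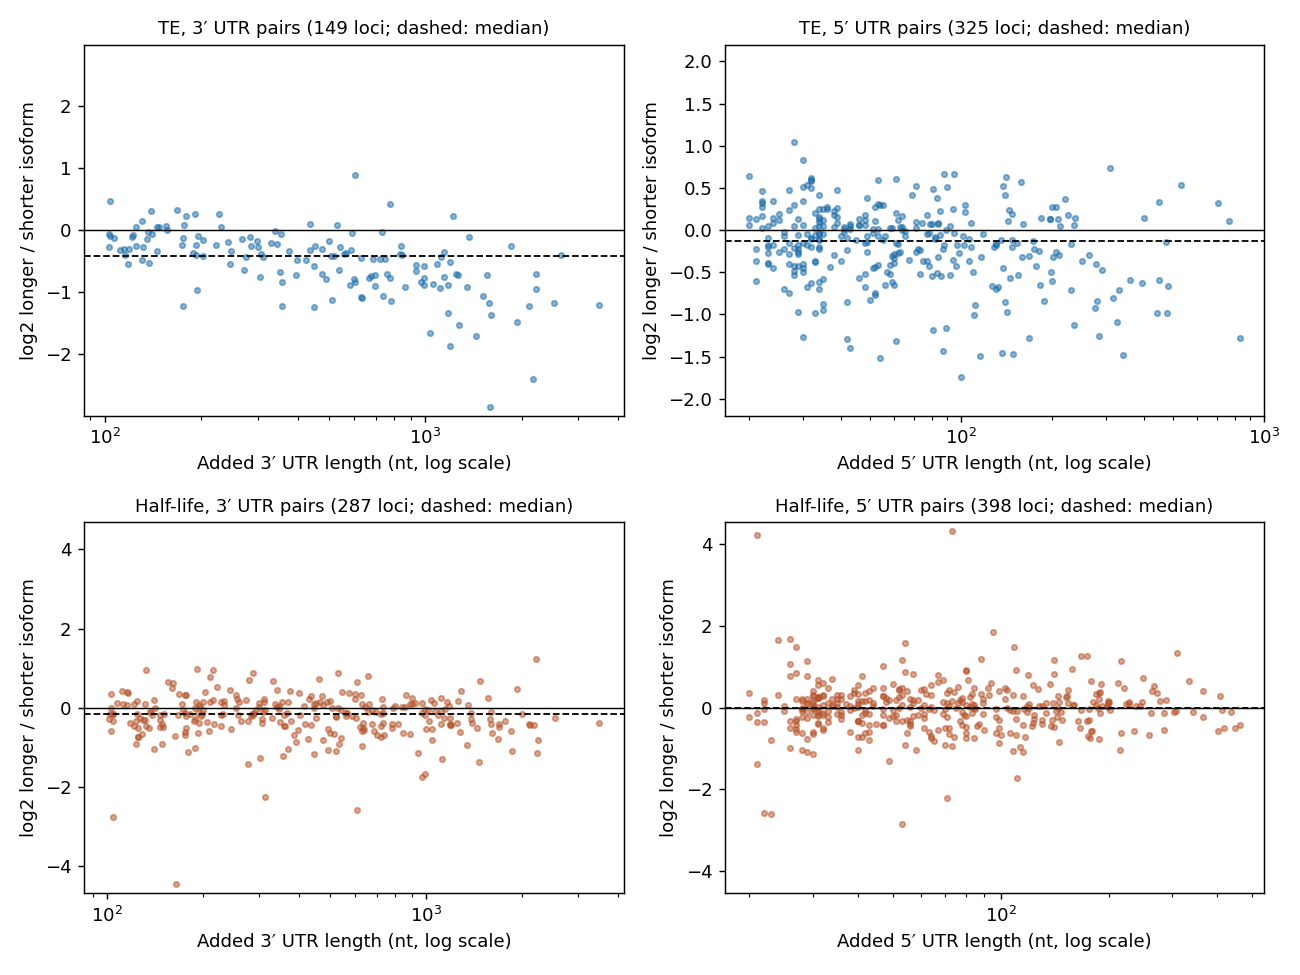
Each point is 1 locus, with log2 of the value of the longer over the shorter isoform on the y axis and the added UTR length in nt on the log x axis; upper row TE, lower row half-life, left 3′ UTR, right 5′ UTR, dashed lines the medians. TE of the longer isoform was lower in 130 of 149 3′ pairs, and half-life differences of 5′ pairs centred on 0.00.

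Half-lives varied with several features of the 3′ UTR. Isoforms with 3′ UTRs of at most 150 nt had a median half-life of 11.5 (11.2 to 11.8, 1203 isoforms), and those above 1200 nt had 9.54 (9.22 to 9.88, 300 isoforms). AUUUA pentamers, the core of AU-rich elements bound by decay factors, went with shorter half-lives: 11.3 (11.1 to 11.4) in 3302 isoforms without one and 8.89 (8.41 to 9.23) in 101 isoforms with 4 or more. The highest quartile of isoforms by 3′ GC content had a median of 11.6 (11.3 to 11.8), and the lowest 9.79 (9.58 to 10.02). Isoforms with a Pumilio motif had a median of 9.67 (9.27 to 10.3, 285 isoforms), against 10.9 (10.8 to 11.02) without. The Spearman correlation with half-life was -0.175 (-0.208 to -0.141) for 3′ UTR length, -0.180 (-0.208 to -0.152) for pentamers and 0.210 (0.178 to 0.239) for 3′ GC content, each with an adjusted p of 2.4e-05. All 4 features passed after correction for UTR lengths and coverage, with 0.229 for 3′ GC content, -0.117 for pentamers and -0.0510 for the Pumilio motif (adjusted permutation p = 0.0181). A TOP start went with a longer half-life, 12.0 (11.4 to 12.4) against 10.8, which did not pass after correction (adjusted permutation p = 0.525). For 5′ UTR length rho was -0.0249 (-0.0569 to 0.00763) across isoforms; with 1 isoform per locus it was -0.0609 (adjusted permutation p = 0.00175), and after correction the adjusted p was 0.498.

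**Figure D3:**
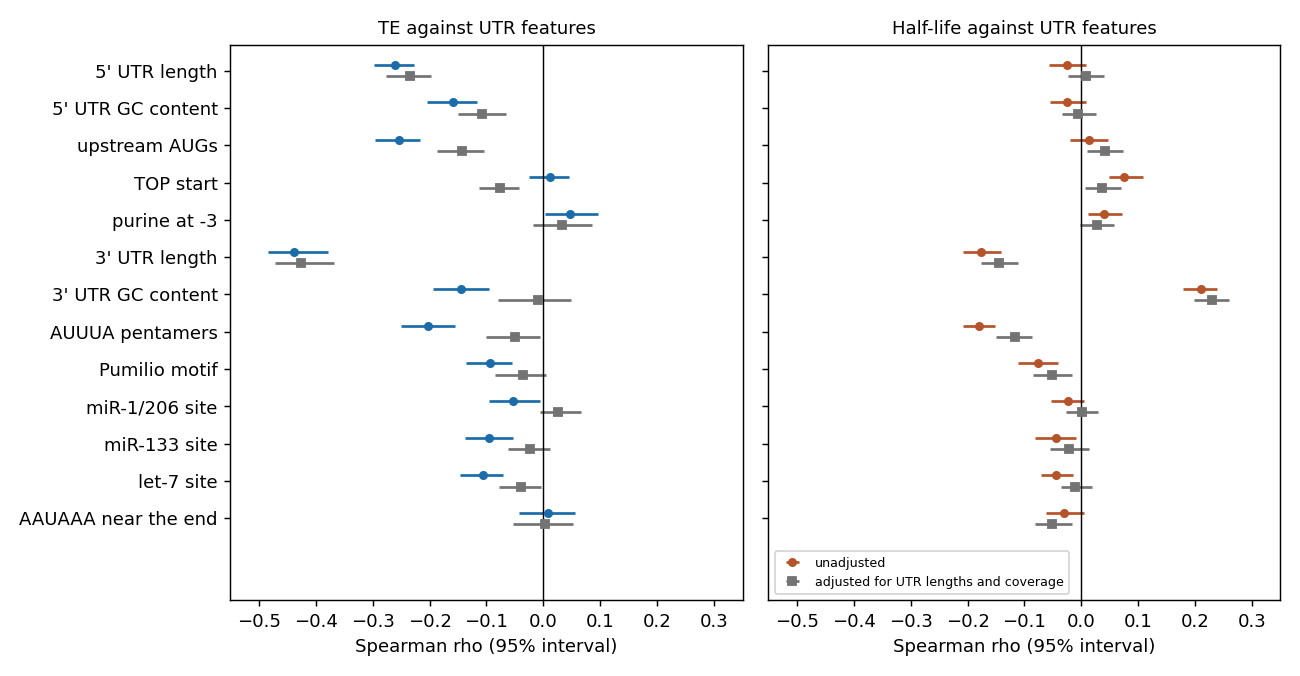
Spearman's rho of TE (left) and half-life (right) with 13 UTR features across isoforms, unadjusted (circles) and adjusted for both UTR lengths and coverage (squares), with 95% intervals from resampling loci. For TE 3′ UTR length lies farthest from 0 at -0.439, and for half-life 3′ GC content at 0.210.

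Within loci, isoforms with the longer 3′ UTR had the shorter half-life. Over 287 loci the median log2 difference was -0.17 (-0.22 to -0.13), a ratio of 0.890, and half-life was shorter in 185 loci (64.5%; adjusted p = 4e-05, permutation test). By added length it was -0.17 (-0.30 to -0.13, 78 loci) for 100 to 200 nt, -0.06 (-0.18 to 0.08, 66 loci; adjusted permutation p = 0.168) for 200 to 400 nt, -0.15 (-0.37 to -0.01, 72 loci) for 400 to 800 nt and -0.29 (-0.41 to -0.13, 71 loci) above 800 nt. Over 398 loci with different 5′ ends the median was 0.00 (-0.04 to 0.05; adjusted permutation p = 0.976). Among these, the 127 loci gaining an upstream AUG had a median of 0.07 (-0.01 to 0.12) and the other 271 had -0.02 (-0.09 to 0.04; adjusted permutation p = 0.129 for the difference), while at equal added length the gain went with 0.15 log2 (0.01 to 0.28). Whether the 3′ and 5′ differences differ was not tested. Loci whose longer 3′ UTR gained a pentamer had a median of -0.20 (-0.39 to -0.14, 129 loci), and the others -0.16 (-0.20 to -0.06, 158 loci; adjusted permutation p = 0.129 for the difference). Single half-lives were noisy, with an SD of 0.844 log2 between isoforms with 3′ ends under 50 nt apart (77 loci). Among pairs with a coverage of at least 300, the largest fall was on chromosome 10, plus strand, from 28.2 for the isoform from 79518076 to 79523929 (36 nt of 3′ UTR) to 11.8 for that ending at 79524230 (337 nt). The largest rise was on chromosome 6, minus strand, from 9.99 for the isoform from 128407641 to 128415621 (98 nt) to 12.9 for that from 128407070 (669 nt), a log2 difference of 0.37, within the SD of near-identical pairs. Both loci were picked by their values.

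New ends were then compared with annotated isoforms of the same locus that shared the other end. Unlike the pairs above, these did not require nested UTRs, equal start and stop codons or a minimum distance, and may share isoforms with them. Isoforms with a shortened 3′ end had higher TE, by 0.39 log2 (0.31 to 0.49), in 64 of 74 loci (adjusted p = 8e-05, permutation test over 8 comparisons), and a longer half-life, by 0.11 (0.02 to 0.17), in 85 of 142 loci (adjusted p = 0.00792). The latter did not pass at a coverage minimum of 15 (0.10, 175 loci; permutation p = 0.0703). Isoforms with an extended 3′ end differed by 0.11 in TE (-0.39 to 0.25, 23 loci; adjusted permutation p = 0.748) and by -0.09 in half-life (-0.29 to 0.13, 60 loci; adjusted p = 0.748). Isoforms with an extended 5′ end differed by -0.32 in TE (-0.67 to 0.03, 34 loci; adjusted permutation p = 0.117), and those with a shortened 5′ end by 0.10 (0.05 to 0.24, 169 loci). The test of the mean did not pass for the last of these (adjusted permutation p = 0.748), although the interval of the median excludes 0. These values depended on the coverage minimum: at 60, TE differed by -0.10 for extended 5′ ends (18 loci; permutation p = 0.0844), 0.23 for shortened 5′ ends (91 loci) and 0.19 for extended 3′ ends (11 loci), and half-life by -0.18 for extended 3′ ends (27 loci). At 15, TE differed by 0.06 for shortened 5′ ends (268 loci) and by 0.0081 for extended 3′ ends (47 loci). Half-life differed by -0.01 (38 loci) and 0.00 (221 loci) for extended and shortened 5′ ends, with adjusted permutation p of 0.513 and 0.748.

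The title of the study names interactions between the UTRs. In a linear model of log2 TE on the log2 lengths, each doubling went with -0.11 (-0.13 to -0.09) for the 5′ UTR and -0.22 (-0.24 to -0.20) for the 3′ UTR, and the product term was 0.0121 (0.000777 to 0.0238), so that long UTRs together lowered TE slightly less than the sum of both terms. A division of TE by transcript length would by itself give a positive product term. For half-life the 3′ term was -0.05 (-0.06 to -0.04) and the product -0.00193 (-0.00767 to 0.00429). All 4 combinations of a short and a long UTR on each side were present in 10 loci with TE. There the combination of both long UTRs departed from the sum of the single differences by a median of -0.05 log2 (-0.22 to 0.05), below 0 in 6 of 10 loci (p = 0.312, exact sign-flip test). In the 13 loci with half-lives it was -0.20 (-0.51 to -0.05), below 0 in 11 of 13, while the test of the mean gave p = 0.228 (exact sign-flip test). At a coverage minimum of 15 the medians were -0.09 for TE (21 loci; permutation p = 0.261) and -0.07 for half-life (19 loci; permutation p = 0.787). The log2 odds ratio of long with long ends in coverage had a median of 0.00 (-0.23 to 0.51) in the 10 loci with TE. In the 13 loci with half-lives it was -0.10 (-0.35 to 0.20), and neither passed (exact sign-flip p = 0.455 and 0.215). A locus entered only if all 4 combinations reached the coverage minimum, so loci whose ends are strongly joined can lack a combination and drop out. Whether long 5′ ends go with long 3′ ends therefore cannot be decided from these odds ratios. Single loci passed Fisher's exact test (adjusted over loci) on their pooled counts, which covers counting error only: with TE 2 joined long with long and 1 long with short, and with half-lives 1 long with short.

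Isoforms with higher TE had longer half-lives on average. Over 1691 isoforms of 1313 loci measured in both assays, Spearman's rho between TE and half-life was 0.214 (0.168 to 0.260) and Pearson's r of the log2 values 0.127 (0.0801 to 0.177), each with a permutation p of 1e-05, the smallest possible. The median half-life was 10.6 (10.3 to 10.9) in the lowest quartile of isoforms by TE and 12.3 (11.9 to 12.5) in the highest, 423 isoforms each. After correction for both UTR lengths and both coverages rho was 0.0865 (0.0348 to 0.139; permutation p = 2e-05), and in the 659 isoforms above the median coverage in both assays, without that correction, it was 0.331. Coding length was not corrected for, so a scaling of TE by transcript length could still enter this relation.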

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

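Coverage outside the UTR comparisons of the report is listed first, and 3 patterns of the report are then weighed. The tests on transcript length and on pairs that gain no pentamer were chosen only after the results were seen. Intergenic isoforms, which carry no UTR sequences and entered no UTR comparison, held a coverage of 30841 in the polysome libraries (155 isoforms) and of 45839 in the decay libraries (135 isoforms). The most covered, on chromosome 6, plus strand, from 57994470 to 57994961, had a coverage of 4397 and 8772 and a half-life of 13.3. The 93 nuclear intergenic isoforms with a half-life and a coverage of at least 30 had a median of 11.9 (95% interval 10.8 to 13.01), and their 76 loci did not pass a permutation test against other loci (p = 0.209). Mitochondrial isoforms held a coverage of 1390 in the polysome libraries and of 3504 in the decay libraries.

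TE was lower in isoforms with an added 3′ UTR. Unequal coverage of both isoforms is argued against by a mean difference of -0.51 at equal coverage (-0.59 to -0.43), against a mean of -0.51 without that adjustment. AUUUA pentamers as the whole cause are argued against by a median of -0.38 in pairs that gain none (-0.47 to -0.28). A part played by pentamers stays open, at 0.0813 at equal added length (-0.12 to 0.27). If TE was divided by the length of the mRNA, a fall free of noise cannot pass the limit set by the UTRs alone. Of the 149 pairs, 79.9% lay between 0 and that limit, just short of the 80% set for this test. A further 11 fell past it and 19 rose. Shuffling the differences among pairs gave a median of 67.8% and at most 74.5%. Falls that grow with added length for another reason could exceed this too, which was not tested. In 17 loci that look free of introns, multiplying TE by the span brought the median absolute difference to 0.586 of its size. The interval was 0.221 to 1.21, and that it must exclude 1 was required only after the value had been seen. In these loci the median difference in TE was -0.11 log2 and did not pass (p = 0.109, sign-flip permutation test). The check therefore says little about the fall in the 3′ pairs. Division by length may play a part but cannot be told apart from a lower ribosome load, because the formula is not given in the sources used here.

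Half-life was longer at higher coverage, with rho = 0.284 (0.258 to 0.307) over 5247 nuclear isoforms. Among the 4822 with both UTR sequences, the median was 9.46 at a coverage of 30 to 49 and 12.3 at 1000 or more. That stable mRNAs gain coverage in the decay libraries themselves is argued against as the whole cause, because coverage in the separate polysome libraries also went with half-life (rho = 0.147, 0.109 to 0.186, against 0.252 for decay coverage in the same 2244 isoforms). A downward bias at low counts may contribute, but its test cannot tell it from stable isoforms gaining coverage, because counts are pooled over all times. In 276 loci with near-identical isoforms the half-life ratio went with the coverage ratio (rho = 0.146, 0.0252 to 0.264, permutation p = 0.0147). The isoform with more coverage had the longer half-life in 56% of these loci, which did not pass a sign-flip permutation test of the mean (p = 0.243). No biological explanation was tested.

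Half-life was shorter in isoforms with an added 3′ UTR. Unequal coverage is argued against by a mean difference of -0.23 at equal coverage (-0.30 to -0.16), against a mean of -0.23 without that adjustment. Pentamers as the whole cause are argued against by a median of -0.16 in pairs that gain none (-0.20 to -0.06). Pentamers may add to the difference, at -0.12 at equal added length (-0.25 to 0.01). That interval holds 0, so a share of the difference due to them cannot be told apart from none.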

How the results depend on the processing

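No paired analysis was possible because the tables hold no values of single libraries; for the same reason the alternatives on pseudocounts, mouse as a block, left-out libraries, other tests, 12 h against 0 h and heavy against light were not run. Of 104 values under alternatives for 47 results, 83 kept their direction and side of the threshold or, for counts of features, stayed within 1.5 times. A further 28, for features with the most abundant isoform per locus, use the p of the reported value and could change in direction only, so they are not counted. The adjustments for UTR length and coverage, the mean over all pairs, and the alternatives for new ends, gained AUGs and loci with 4 combinations were chosen after seeing the data. The 3′ pair differences, the TE differences of 5′ pairs, the product term for TE and the relation of TE to half-life kept both under all their alternatives. Corrected for UTR lengths and coverage, 5 features passed for TE in place of 10 and 4 for half-life in place of 6, and rho turned to -0.0770 for TE with a TOP start, 0.0262 for TE with miR-1 sites, 0.00887 for half-life with 5′ UTR length and 0.00123 for half-life with miR-1 sites. With the most abundant isoform per locus, half-life had a rho of -0.0126 with upstream AUGs and a product term of 0.000607. Half-life differences of 5′ pairs, not past the threshold, turned to -0.0026 at the doubled distance and -0.0057 at a coverage minimum of 15. At that minimum, half-life differed by -0.0117 for shortened 5′ ends, and by 0.10 for shortened 3′ ends, no longer past the threshold (permutation p = 0.0703). At a minimum of 60, extended 5′ ends differed by 0.0245 in half-life and -0.10 in TE (permutation p = 0.0844). At that minimum, the median log2 half-life of the longer over the shorter isoform was 0.13 higher in pairs gaining an upstream AUG than in other pairs. The difference of the means passed (permutation p = 0.0436). A further 7 feature relations no longer passed under 1 alternative or another, mostly the same correction, and 1 newly passed. The cause was not tested. Half-lives of near-identical isoforms (276 loci, SD 0.731 log2) spread more at low coverage, with an SD of 0.861 in the 138 loci with a lower coverage of at most 57.5 and 0.573 in the other 138 (permutation p = 0.00988 for the absolute differences), a split made after seeing the data.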

Other observations

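Mitochondrial isoforms had low TE. The 8 mitochondrial isoforms with a TE and a coverage of at least 30 ran from 6.2e-05 to 0.000186 with a median of 0.000145, and 1.19% of 3517 nuclear isoforms lay below the highest of them. The nuclear median was 0.000742, 5.13 times as high. Of the 8, 6 span 4596 to 10132 nt, and the annotated isoform from 5328 to 6941, with a higher TE of 0.000357, has a coverage of 24 and is not among them. Mitochondrial mRNAs are translated inside the organelle, on ribosomes of their own. Of 34 mitochondrial isoforms with a half-life and that coverage, the median was 7.63, against 10.8 for 5247 nuclear isoforms. That median is not one of mRNAs alone, because isoforms classed as intergenic, among them those starting at positions 70 and 1673, are included. The isoform from 9877 to 11544 had a half-life of 3.69 (coverage 101), that from 2751 to 3705 had 2.99 (coverage 30), 4 isoforms starting at position 70 had 9.24 to 26.2, and the highest value, 219, was that of the isoform from 1673 to 1986 (coverage 71). These isoforms overlap on a single small chromosome, so no test was made.

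In the polysome table, 74 isoforms had an end more than 100000 nt from the annotated end, with a median coverage of 19, a highest coverage of 828 and a span of up to 1992959 nt; in the decay table there were 37, with a median coverage of 43 and a highest of 3870. A locus held up to 44 isoforms in the polysome table. The 10 most covered isoforms held 11.3% of the polysome and 10.7% of the decay coverage.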
